A study of Mus musculus with 2 samples.

How the data were processed

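A pool of sorted cells from 5 mouse organoid cultures, 2 control and 3 Etv1 mutant, was sequenced as an RNA library and a hashtag library. Deposited were 1 matrix of hashtag counts, with 5 hashtags over 3409 barcodes, and 1 matrix of estimated RNA counts (expected counts per gene and cell), with 22253 genes over the same barcodes. The hashtag values are whole, and 95.6% of the RNA values above 0 are whole, the rest being fractions. Per the submitters' processing notes, Cell Ranger 6.1.0, alevin, Salmon 1.4.0, Seurat 4.3.0 and the build mm10 were used. The part each tool played is not given in the sources used here. Which hashtag belonged to which culture came from the labels. The nature of the Etv1 mutation and the sort gate are not stated there. Libraries were not normalized before deposit as far as the values show, and 6446 genes had no count.

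Barcodes were assigned to cultures with HTODemux in Seurat 5.3.0 (SeuratObject 5.2.0) on centred log-ratio hashtag counts with a positive quantile of 0.99, which set thresholds of 12, 34, 18, 12 and 35 counts for the 5 hashtags. This gave 1814 single-culture barcodes, 273 with several hashtags and 1322 with none. Barcodes had to hold at least 500 detected genes, which 237 failed, and at most 25% mitochondrial counts, which 547 failed. Barcodes with several hashtags were removed as doublets between cultures. Scrublet, run through scanpy, marked 4 of 2725 filtered barcodes (0.147%), 1 of them among the analysed cells and 0 among enteroendocrine-like cells, so doublets within a culture may remain. MULTIseqDemux placed 1437 of the 1438 barcodes that both methods called in the same culture. Of the barcodes that HTODemux placed in control culture 2, however, it gave several hashtags to 81 and none to 91, against 42 to 56 and 1 to 3 for each of the other cultures. A fixed rule, the top hashtag holding at least 70% of at least 10 counts, kept 4, 126, 17, 8 and 47 filtered cells.

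Cells were clustered with scanpy 1.11.5 (Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, igraph 0.11.9): counts scaled to 10000 per cell and log-transformed, 2000 variable genes, 30 principal components, 15 neighbours, Leiden resolution 0.8, and no integration between cultures. A cluster took a name from the fixed marker lists if at least 3 markers had a log2 fold of at least 0.5 and were found in at least 25% of its cells, after its top 10 genes had been examined. A cluster stayed unnamed if its cells lay more than 3-fold below the median UMIs of their own culture and no marker of the list was among its top 10 genes. This held for cluster 6, with 6 of 8 stem markers past those bounds, and for cluster 9, with 6 of 10 Paneth markers. A cluster with more markers of another list than of its own in its top 10 also stayed unnamed. The classes are rebuilt from these data, and no annotation by the submitters was used here. No enteroendocrine-like sub-class had 20 cells in every culture, so none was tested. Figures were drawn with matplotlib 3.10.9.

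Estimated counts were summed per culture over all cells or over the cells of a class and then rounded to whole numbers, so that the cultures, not the cells, were the replicates. Genes were tested as mutant minus control with the quasi-likelihood test of edgeR 4.0.16 (R 4.3.3), TMM scaling, filterByExpr and Benjamini-Hochberg adjustment, with an adjusted p under 0.05 taken as passing. The median log2 fold change of all genes tested over all cells was 0.00. In the planned gene tests, classes needed at least 20 cells in every culture, apart from the enteroendocrine-like class, which was fixed as a main comparison whatever its size. A genotype by class term with culture as a block was fitted for stem-like and cycling-like cells. Class shares were tested with edgeR on cell counts, with the cells of the culture as library size. Gene lists with at least 3 tested members were tested with camera in limma 3.58.1 at a preset correlation of 0.01, with an estimated correlation and with fry, adjusted over lists. Shares of cells with a hormone UMI were computed after thinning each cell to the 10th percentile of UMI totals and compared by a two-sided exact permutation test over the 10 splits of 5 cultures, whose smallest p is 0.1. Exact binomial and Poisson intervals at 95% and the limits set by a count of 0 (3 counts) cover counting error only. Positions are those of GENCODE vM21 on mm10, in which 22109 genes (99.35%) had 1 position. H3c7 had none.

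Groups, tests, gene lists, marker lists and most alternatives were chosen before the data were examined. The named genes were Etv1, every tested hormone gene, the up to 8 genes with the largest rise and 8 with the largest fall that passed without overlap between groups (4 and 4 in other classes; where none passed, the 3 smallest p values in each direction), and the up to 4 members with the smallest p of each list, of which the text gives examples. Other names were chosen after their values were seen. The lists were hormones and hormone-making enzymes, enteroendocrine transcription factors, secretory granule genes, nutrient sensing, the serotonin pathway, Notch, ERK feedback and PEA3-family genes, Wnt targets, immediate early genes, unfolded protein and integrated stress, p53 targets, cholesterol synthesis, ileal and proximal intestine genes, interferon response, mitochondrially encoded genes, genes whose symbols start with Rps or Rpl, markers of 6 enteroendocrine groups and of stem, cycling, enterocyte, goblet, Paneth, tuft and M cells, and markers of immune, mesenchymal, endothelial and neuronal or glial cells. Lists overlap, so their results are not independent. The hormone symbol Mln matched only by synonym to Mrln, which encodes the muscle peptide myoregulin rather than a hormone. It was not tested. Hist1h1b is named H1f5 here.

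Alternatives were DESeq2 1.42.0, no count filter, library sizes without the 20 most abundant genes, the 70% rule, MULTIseqDemux, no cell filter, a stricter filter (at least 1000 genes and at most 15% mitochondrial counts), removal of Scrublet doublets, 197 cells drawn from each culture, Leiden resolutions 0.4 and 1.2, hormone genes left out of clustering, and each culture left out in turn. With 1 control culture left, the spread was estimated from the mutant cultures alone. Added after seeing the data were HTODemux on hashtags scaled within each cell, hormone genes left out of clustering in gene tests, tests of the remaining clusters, and removal of the cell with the most Pyy UMIs in each culture. Barcodes with no or several hashtags by the calls in use entered no comparison.

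The tests were tried on simulated counts with 200 genes changed, drawn from the real means and library sizes. Over all cells (10958 genes) 57.6% of 2-fold, 98.4% of 4-fold and 98.5% of 16-fold changes were recovered, with 17 false among 182 calls. In enteroendocrine-like cells (1791 genes) the shares were 15.6%, 93.0% and 100%, with 4 false among 127 calls. They were 55.4%, 100% and 100% in cycling-like and 80.6%, 98.4% and 100% in stem-like cells. In enterocyte-like cells they were 31.8%, 92.1% and 100%, and for the class term 41.8%, 91.0% and 97.0%. False calls were 12 among 175 (6.86%) in cycling-like and 16 among 192 (8.33%) in stem-like cells. In enterocyte-like cells they were 17 among 157 (10.8%), and for the class term 19 among 172 (11.0%). All 3 lists with doubled genes were called in both main comparisons with the preset correlation, beside 1 of 17 unchanged lists over all cells and 0 of 10 in enteroendocrine-like cells. With an estimated correlation 2 of the 3 were called over all cells and 1 of the 3 in enteroendocrine-like cells. For class shares the enteroendocrine-like class alone was raised in the mutant cultures. There, 20.5% of 2-fold and 70% of 4-fold rises were recovered in 200 draws. Falls and changes of other classes were not simulated, and the spread between cultures was assumed rather than estimated from the data. The simulation drew counts per culture and did not model a hormone made by a few cells. For the class term, stem-like and cycling-like counts were drawn independently and only stem-like ones were changed. Effects of a culture shared by both classes were thus not modelled.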

Results

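Single-cell RNA sequencing was used to compare control and Etv1 mutant cultures of mouse distal small intestinal epithelium, grown as organoids, which are three-dimensional epithelial cultures that keep dividing and form the differentiated cell types of the gut lining. Etv1 encodes a transcription factor of the PEA3 group of the ETS family. All cultures carried the Neurog3-RFP and Gcg-Venus reporters, which mark cells entering the enteroendocrine lineage and cells that express proglucagon. The question was which genes and cell types differ when Etv1 is mutated. Cells were sorted (the gate is not stated in the labels), tagged by culture with hashtag oligonucleotides, pooled and sequenced, so that each culture was recovered from hashtag counts. There were 2 control and 3 mutant cultures, which the labels call biological replicates. The count matrix held 3409 barcodes and 22253 genes, and 2725 barcodes passed the cell filter. Of these, 1432 were assigned to 1 culture: 323 and 349 cells to control cultures 1 and 2, and 282, 281 and 197 cells to mutant cultures 1, 2 and 3. Summed RNA counts per culture ranged from 4193171 to 7254352 unique molecular identifiers (UMIs), with medians of 20842 to 24126 UMIs per cell. The hashtags were shallow: a barcode held a median of 71 hashtag counts, of which the most abundant hashtag took a median of 43.4%. No hashtag was assigned to 1054 filtered barcodes, and 239 carried more than 1.

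The 1432 cells formed 10 clusters, of which 7 could be named from markers fixed before the data were examined. Stem-like cells (272; Olfm4, Gkn3) and cycling-like cells (283 in 2 clusters; Ube2c and Nusap1 led one, Pclaf and Rrm2 the other) were the largest named classes. Enterocyte-like cells (237) came from a cluster led by Apoa1 and Apoc3 and a cluster led by Lgals3, Sprr2a3, Areg and Anxa1. Areg and Anxa1 are also induced in injured epithelium. The latter cluster (157 cells) had 9 of 12 enterocyte markers past the naming bounds but 0 among its top 10 genes. Goblet/Paneth-like cells (106; Fcgbp, Spink4, Lyz1) numbered 13 in the culture with fewest and were left out of the planned gene tests. Enteroendocrine-like cells (54; Chga, Chgb, Neurod1, Neurog3) numbered 16 and 14 in the control cultures and 7, 9 and 8 in the mutant cultures. Cluster 2 (188 cells) had Atf5, Psat1 and Asns among its top 10 genes. Cluster 6 (212 cells, median 6182 UMIs) had Olfr46 first, with mitochondrially encoded genes among the others. Cluster 9 (80 cells, median 1342 UMIs) had Gm49804 and Gm10358 first, with defensin genes among the others. All of these stayed unnamed.

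Etv1 transcripts were sparse and lay almost entirely in enteroendocrine-like cells, which held 87 of 89 control and 48 of 53 mutant Etv1 counts. Over all cells, Etv1 stood at 6.27 ± 0.0388 CPM (counts scaled to 1e6 per culture; SD, n = 2) in control and 3.12 ± 0.0522 CPM (SD, n = 3) in mutant cultures, from 45 and 44 counts against 20, 20 and 13. The log2 fold change of mutant over control was −1.0 (SE 0.22; edgeR quasi-likelihood test, adjusted p = 1). The difference did not pass across all genes, although the 2 groups did not overlap. The pooled ratio of mutant to control was 0.50, with a 95% interval of 0.349 to 0.711 for counting error only. Within enteroendocrine-like cells the level was 309.4 ± 64.9 CPM (SD, n = 2) in control and 223.5 ± 35.5 CPM (SD, n = 3) in mutant cultures (log2 fold change −0.46, SE 0.30, adjusted p = 0.946). There, 8 of 16 and 9 of 14 control cells against 1 of 7, 3 of 9 and 2 of 8 mutant cells held an Etv1 count. Single cells weighed heavily, since 1 cell held 17 of the 20 Etv1 counts of mutant culture 1 and 1 cell held 16 of the 20 of mutant culture 2. In all cells the value moved to −1.96 with equal cell numbers per culture or with hashtags scaled within each cell, to −0.57 with MULTIseqDemux calls and to −0.63 without the cell richest in Pyy of each culture. Within enteroendocrine-like cells it moved to −0.69 without control culture 1, −0.24 without control culture 2, −1.05 with scaled hashtags and −1.74 with equal cell numbers, and it passed under none of these. Etv1 lies at chromosome 12, positions 38779380 to 38870484 on the plus strand (mm10). The labels do not state the mutation, and a mutant allele can still give transcripts that are counted, so these levels may check nothing about it.

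Across all cells, Pyy was the gene that fell. Pyy encodes peptide YY, a satiety hormone of distal enteroendocrine cells. It stood at 132.6 ± 1.79 CPM (SD, n = 2) in control and 2.36 ± 0.858 CPM (SD, n = 3) in mutant cultures, 56.1-fold lower (log2 fold change −5.86, SE 0.18, edgeR adjusted p = 6.02e-05), from 939 and 944 counts against 11, 13 and 14. Pyy lies at chromosome 11, positions 102106676 to 102107832 on the minus strand (mm10). Nearly all control counts came from 1 cell per culture, with 927 UMIs in control culture 1 and 895 in control culture 2. Without the cell richest in Pyy of each culture, an alternative chosen after seeing the data, the log2 fold change was −1.10 (SE 0.62) with an adjusted p of 1, and no gene passed. With equal cell numbers per culture it was −5.48 (SE 1.39) with an adjusted p of 1, and the range over all alternatives was −6.17 to −1.10.

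No gene rose across all cells in the edgeR test, which took 11061 genes. At an unadjusted p under 0.05, 133 genes were higher and 204 lower, 337 together against 553 given by chance. DESeq2 called 9 genes, with Igfbp4 and Ly6d higher and Pyy, Reg4, Spink4, Col16a1, Muc2, Ang4 and Clps lower. Among genes that did not pass in edgeR, Ly6d, a surface protein, had the smallest p (log2 fold change 1.17, SE 0.11, adjusted p = 0.0597; 21.5 ± 1.10 CPM in control and 48.6 ± 3.04 in mutant cultures). Next came Igfbp4, a secreted binding protein of insulin-like growth factors (2.85, SE 0.35, adjusted p = 0.245; 4.87 ± 1.14 and 35.0 ± 12.4 CPM). Spink4, a secreted peptide of goblet cells, had the smallest p below zero after Pyy (−0.70, SE 0.13, adjusted p = 1), and Ly6e, a surface protein of the family of Ly6d, the third smallest above zero (1.53, SE 0.39, adjusted p = 1). Scgn and Scg3, both of the secretory granule list, stood at −1.97 (SE 0.36) and −2.32 (SE 0.43), also without passing. Groups did not overlap in 1851 genes (16.7%; chance gives 20%). Leaving out control culture 1 raised the count to 6 genes (Zg16, Sct, Muc2, Lyz1 and Ly6e beside Pyy). Leaving out control culture 2 raised it to 5 (Defa22, Defa29, Defa2 and Nts beside Pyy), and leaving out mutant culture 2 to 3 (Igfbp4 and Ly6d beside Pyy). Without a control culture the spread came from the mutant cultures alone, here and below, so calls gained that way rest on 1 control culture.

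Hormone genes were lower in sum. Of 9 tested hormone genes and hormone-making enzymes, 8 were below zero, Pyy passed among all genes, and Pyy, Sct and Nts passed when adjusted over the list alone. Sct (secretin) stood at −2.30 (SE 0.50), Nts (neurotensin) at −6.67 (SE 1.94) and Ghrl (ghrelin) at −3.61 (SE 1.81). Tph1, the enzyme that starts serotonin synthesis, stood at −2.21 (SE 1.17). Cck (cholecystokinin) stood at −1.30 (SE 1.17), Tac1 (substance P) at −0.90 (SE 1.27), Gcg (proglucagon) at −0.63 (SE 1.2) and Adm (adrenomedullin) at 0.35 (SE 0.49). Apart from Pyy, all had an adjusted p of 1 among all genes. Gip and Vip had no count in any culture. Several of these hung on single cells: 1 cell of control culture 1 held 1746 Nts UMIs and 1 cell of control culture 2 held 2312 Ghrl UMIs. Without control culture 1 the log2 fold change was 5.89 for Nts, 4.08 for Tac1, 0.21 for Tph1 and −2.97 for Sct (adjusted p = 0.0130). Without control culture 2 it was 0.42 for Gcg, 0.72 for Cck, 3.98 for Ghrl, −1.01 for Sct and −7.68 for Nts (adjusted p = 0.0034). Sct stood at 79.9 and 313.2 CPM in the control cultures. The list passed as lower (camera, preset correlation, adjusted p = 3.09e-05; adjusted p = 0.128 with an estimated correlation).

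Among the other enteroendocrine gene lists, 3 were lower across all cells, where enteroendocrine-like cells made up 4.48% ± 0.666 of control (SD, n = 2) and 3.25% ± 0.790 of mutant cultures (SD, n = 3). In the secretory granule list 19 of 22 members were below zero. Of these, 6 were lower adjusted over the list alone and none among all genes, among them Scgn, Scg3 and Pcsk1n (−2.37). The list passed (adjusted p = 2.7e-09; adjusted p = 0.128 with an estimated correlation). General enteroendocrine markers, which share those 3 genes, were below zero in 9 of 11 (adjusted p = 1.2e-08; adjusted p = 0.128 with an estimated correlation), with 5 lower adjusted over the list alone. Markers of the L/I/N subtypes, which make proglucagon, cholecystokinin and neurotensin, were below zero in 6 of 6 (adjusted p = 2.4e-08; adjusted p = 0.128 with an estimated correlation). Pyy, Scgn, Sct and Nts of this list were lower adjusted over the list alone, and fry also called it (adjusted p = 0.0398). Enterochromaffin markers did not pass (4 of 6 below zero, 1 lower adjusted over the list alone, Reg4 −1.21, adjusted p = 0.0662). Nor did the serotonin pathway (5 of 10 below zero, Slc18a1 −0.91, 0.469) or enteroendocrine transcription factors (9 of 16 below zero, Neurog3 0.77, 0.469). Likewise, progenitor markers (4 of 8, 0.478), nutrient sensing genes (1 of 3 below zero, Ffar2 −0.68, 0.589) and K/X markers (1 of 3, Ghrl, 0.940) did not pass.

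Enterocyte markers were higher together, with 11 of 12 above zero and none past the test alone (Apoa4 1.07, Fabp1 2.35; adjusted p = 5.06e-06; adjusted p = 0.353 with an estimated correlation). Enterocyte-like cells made up 14.2% ± 3.51 of control and 18.3% ± 4.35 of mutant cultures. Proximal intestine genes were above zero in 5 of 7, with Apoa4, a lipoprotein component, and Fabp1, a fatty acid carrier, higher adjusted over the list alone (adjusted p = 0.00224; adjusted p = 0.167 with an estimated correlation). Paneth markers were below zero in 9 of 9, with 2 lower adjusted over the list alone, among them the antimicrobial Ang4 (−1.24; adjusted p = 7.8e-07; adjusted p = 0.128 with an estimated correlation). Goblet markers were below zero in 7 of 8, with 3 lower adjusted over the list alone, Muc2 (−2.36, the main gut mucin) and Spink4 among them (adjusted p = 0.00169; adjusted p = 0.353 with an estimated correlation). Muc2 stood at 7.97 and 34.0 CPM in the control cultures and at −0.98 without control culture 2 (−3.06, adjusted p = 0.0113, without control culture 1). Goblet/Paneth-like cells made up 8.11% ± 2.71 of control and 7.16% ± 3.51 of mutant cultures. Cluster 9, unnamed but with defensin genes among its top 10, made up 3.11% ± 0.461 and 7.55% ± 1.70. Tuft markers were below zero in 4 of 5 (Dclk1 −1.50, Pou2f3 −1.02; adjusted p = 0.00418; adjusted p = 0.434 with an estimated correlation). Without control culture 2 the enterocyte list no longer passed (adjusted p = 0.275), nor did the goblet list (0.0529), and without mutant culture 1 the tuft list did not (0.729).

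Wnt targets were below zero in 12 of 12 by small amounts (Myc −0.23, Ephb3 −0.35; adjusted p = 1.9e-05; adjusted p = 0.434 with an estimated correlation). Mitochondrially encoded genes were below zero in 13 of 13 (mt-Co3 −0.18, mt-Nd3 −0.20; adjusted p = 2.5e-05; adjusted p = 0.128 with an estimated correlation). Cluster 6, with such genes among its top 10, made up 17.5% ± 2.01 of control and 12.3% ± 2.85 of mutant cultures. The list of genes named after ribosomal proteins was below zero in 81 of 95 with a median of −0.05 (adjusted p = 2.5e-05; adjusted p = 0.741 with an estimated correlation). Its 4 smallest p values included Rps6kb1 and Rps6kc1, kinases that are no part of the ribosome. Unfolded protein and integrated stress genes were below zero in 10 of 12 (Asns, asparagine synthetase, −0.27; Trib3 −0.50; adjusted p = 0.0412; adjusted p = 0.368 with an estimated correlation). No member of these 4 lists passed alone. The stress list no longer passed without control culture 1 (adjusted p = 0.714), mutant culture 1 (0.0709) or mutant culture 3 (0.139), nor the ribosomal list without control culture 2 (0.0546) or mutant culture 1 (0.152).

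The other tested lists did not pass across all cells by the preset correlation. Immediate early genes were above zero in 10 of 13 (Fos 0.35; adjusted p = 0.0584), p53 targets in 6 of 8 (Ccng1 0.29; 0.0995) and ileal genes in 7 of 8 (0.184). ERK feedback and PEA3-family genes were above zero in 9 of 13 (0.672), cholesterol synthesis genes in 7 of 14 (0.940) and interferon response genes in 3 of 5 (Ifi27l2b 0.27; 0.901). Notch pathway genes were below zero in 8 of 11 (Dll4 −0.63; 0.195), stem markers in 6 of 8 (Rgmb −0.27; 0.118) and cycling markers in 5 of 10 (0.940). Median and mean differed in sign for interferon (0.16 and −0.25), K/X (0.13 and −1.10), nutrient sensing (0.07 and −0.17) and serotonin (0.03 and −0.33) genes. The interferon test leaned up and the other 3 down, and cycling markers, with a median of 0.01, leaned down. The D-cell and M-cell lists had 2 tested members each, too few for a test, and the immune, mesenchymal, endothelial and neuronal or glial lists had 0. Of 28 lists tested, 13 passed with the preset correlation, 0 with an estimated correlation (smallest adjusted p = 0.128) and 1 by fry.

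**Figure D1:**
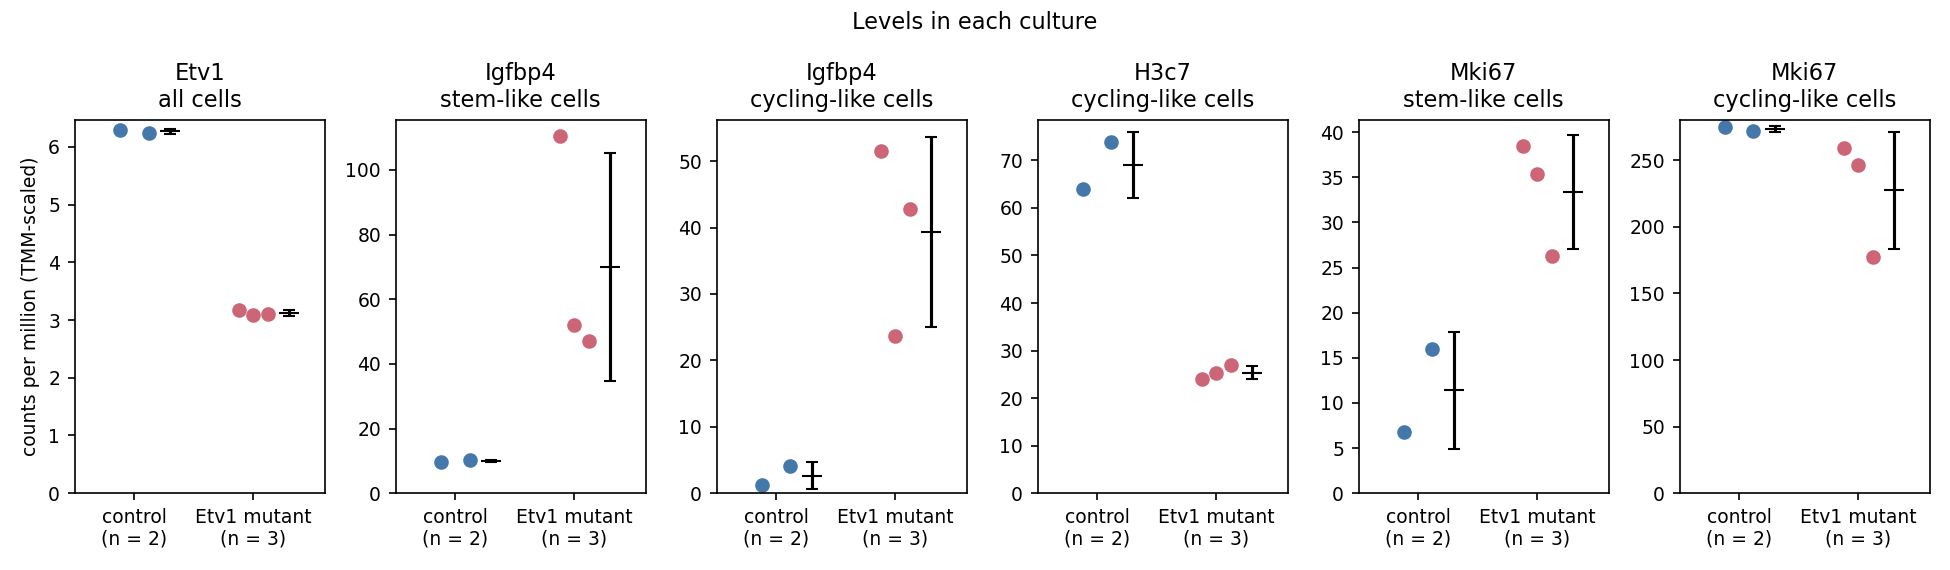
TMM-scaled CPM per culture for Etv1 in all cells, Igfbp4 and Mki67 in stem-like and cycling-like cells and H3c7 in cycling-like cells; points are cultures, and bars are the mean with the SD. Igfbp4 in stem-like cells stood at 9.77 and 10.2 in the control cultures and at 110.5, 52.1 and 47.2 in the mutant cultures.

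Within the enteroendocrine-like class, Pyy fell and was the sole gene called among 1916. Its level was 6580.8 ± 1256.5 CPM (SD, n = 2) in control and 19.2 ± 22.0 CPM (SD, n = 3) in mutant cultures (log2 fold change −8.37, SE 0.56, edgeR adjusted p = 2.07e-04). Counts were 929 and 925 against 0, 3 and 1, a pooled mutant to control ratio of 0.00289 with a 95% interval of 7.86e-04 to 0.00741 for counting error only. The class held 87577 to 210081 UMIs per culture. In control culture 1, 1 of 16 cells held 99.8% of the Pyy counts, and in control culture 2, 1 of 14 held 96.8%. Cells with at least 3 Pyy UMIs numbered 1 and 3 in the control cultures and 0, 0 and 0 in the mutant cultures. If the 4 cells had fallen among the 54 at random, none would have been mutant with a probability of 0.0867, the smallest value these numbers allow. Without the cell richest in Pyy of each culture, Pyy failed the count filter and no gene passed in edgeR. With equal cell numbers per culture Pyy had no value in this class. Ly6e had the next smallest p (2.19, SE 0.34, adjusted p = 0.121; 78.3 ± 19.3 and 366 ± 58.7 CPM). At an unadjusted p under 0.05, 41 genes were higher and 43 lower, 84 against 95.8 given by chance. DESeq2 called 2 genes, Ly6e higher and Pyy lower, and groups did not overlap in 376 genes (19.6%; chance gives 20%). Without control culture 1 the count rose to 9 (Ly6e, Krt20, Sct, Ghrl, Reg4, Scgn, Cd177 and Ceacam10 beside Pyy), and without control culture 2 to 4, Tph1 and Nts among them, each with 1 control culture left to compare.

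The other 6 hormone genes tested in enteroendocrine-like cells did not pass, and their spread was wide. Sct stood at −2.27 (SE 0.86), Tph1 at −2.28 (SE 0.94), Ghrl at −3.42 (SE 2.05), Cck at −0.64 (SE 1.42), Tac1 at −0.05 (SE 1.18) and Gcg at −0.02 (SE 1.51). Adjusted over the list alone, Pyy passed (7.57e-07), and Sct and Tph1 had an adjusted p of 0.0899. Gcg levels were 10593.3 ± 9331.3 CPM (SD, n = 2) in control and 10444.8 ± 12181.5 CPM (SD, n = 3) in mutant cultures. Cells rich in Gcg occurred in both genotypes, with and without Pyy in control cultures. The Pyy-rich cell of control culture 1 held 651 Gcg UMIs. In control culture 2, 1 cell held 1184 Gcg and 895 Pyy UMIs and another 943 Gcg and 0 Pyy UMIs. The Gcg-rich cells of mutant cultures 2 and 3 held 1655 and 519 Gcg UMIs with 1 Pyy UMI each. Of 3902 Cck UMIs of control culture 2, 1 cell held 3822. Cck passed as lower with equal cell numbers (−10.55, adjusted p = 0.00152) and with scaled hashtags (−9.30, adjusted p = 0.00194). Without control culture 1 the log2 fold change of Sct was −3.12 (adjusted p = 8.88e-04) and that of Tph1 −0.27, and without control culture 2 they were −0.07 and −3.04 (adjusted p = 0.0441). Ghrl was at −4.45 (adjusted p = 0.0201) without control culture 1 and at 6.0 without control culture 2, where Cck was at 1.78. Tac1 was at 7.10, 0.52 and 0.09 without control culture 1, mutant culture 2 and mutant culture 3, and Gcg at 1.38, 0.56 and 0.17 without control culture 2, mutant culture 1 and mutant culture 3. Without the cell richest in Pyy of each culture, the log2 fold change of Gcg was 1.09.

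**Figure D2:**
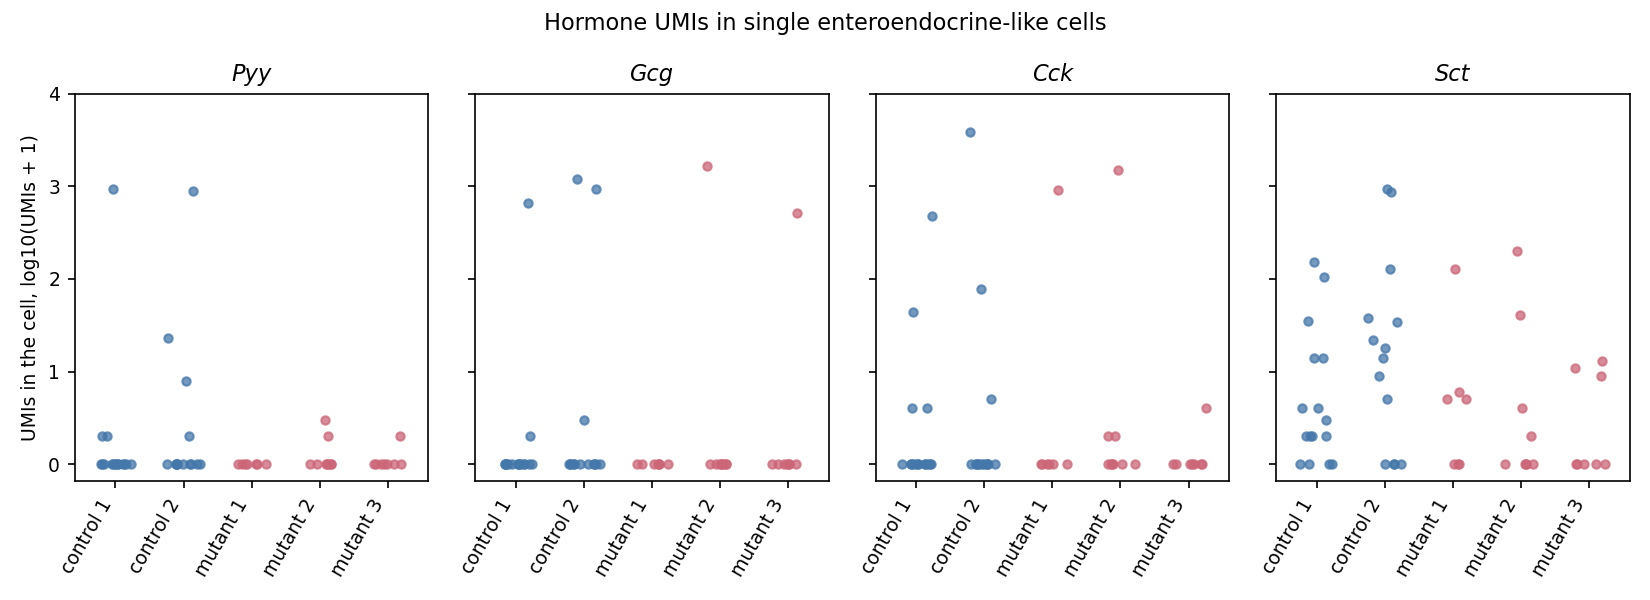
UMIs of Pyy, Gcg, Cck and Sct in each of the 54 enteroendocrine-like cells by culture, on a log10(UMIs + 1) axis; each point is 1 cell. Pyy reaches 927 and 895 UMIs in 1 cell of each control culture and at most 2 UMIs in the mutant cultures.

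Among gene lists in enteroendocrine-like cells, hormone genes were below zero in 7 of 7 (adjusted p = 0.00228; adjusted p = 0.309 with an estimated correlation; fry adjusted p = 0.0399). L/I/N markers were below zero in 5 of 5, with Pyy, Scgn (−1.43) and Sct lower adjusted over the list alone (adjusted p = 7.54e-05; adjusted p = 0.351 with an estimated correlation). Secretory granule genes were below zero in 14 of 16 (Pcsk1n −2.05; adjusted p = 0.0076; adjusted p = 0.309 with an estimated correlation), as were cholesterol synthesis genes in 7 of 9 (Fdps −0.82, Cyp51 −0.85; adjusted p = 0.00279; adjusted p = 0.445 with an estimated correlation). Enteroendocrine transcription factors were above zero in 6 of 7, with 3 higher adjusted over the list alone (Neurog3, the factor that starts the endocrine lineage, 1.37; Sox4 0.95; adjusted p = 0.00279; adjusted p = 0.370 with an estimated correlation). Progenitor markers, which include Neurog3 and Sox4, were above zero in 4 of 4, with 2 higher adjusted over the list alone (adjusted p = 5.38e-04; adjusted p = 0.370 with an estimated correlation). Enterocyte markers were above zero in 3 of 3, with Sis (sucrase-isomaltase, 1.27) higher adjusted over the list alone (adjusted p = 5.38e-04; adjusted p = 0.309 with an estimated correlation). Ribosomal protein genes were above zero in 74 of 87 with a median of 0.15 (Rpl35 0.38; adjusted p = 8.55e-05; adjusted p = 0.547 with an estimated correlation). Apart from Pyy, no member passed among all genes. The hormone list no longer passed without mutant culture 1 (adjusted p = 0.0524), nor did the transcription factors without mutant culture 3 (0.12). Without control culture 1 cholesterol synthesis (0.243) and progenitor markers (0.125) did not pass, nor did the ribosomal list without control culture 2 (0.109) or mutant culture 1 (0.464).

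The other 10 lists tested in enteroendocrine-like cells did not pass. Enterochromaffin markers were below zero in 5 of 6 (adjusted p = 0.075), the serotonin pathway in 5 of 6 (0.118), general enteroendocrine markers in 7 of 10 (0.118) and unfolded protein and integrated stress genes in 4 of 6 (Asns −1.09; 0.327). Immediate early genes were above zero in 8 of 9 (Zfp36 0.95; 0.118), and mitochondrially encoded genes in 11 of 11 (0.210). ERK feedback and PEA3-family genes were above zero in 2 of 3 (Dusp5 0.69; 0.252), goblet markers in 2 of 3 (Tff3 1.89; 0.268) and Paneth markers in 3 of 6 (Defa24 0.65; 0.297). Stem markers were above zero in 3 of 5 with a median of 0.04, while their mean was −0.30 and the test leaned down (Slc12a2 −1.77; 0.210). The remaining 16 lists had fewer than 3 tested members: 2 for nutrient sensing, Notch, p53 and K/X genes, 1 for Wnt targets, proximal intestine genes (Sis) and tuft markers, and 0 for the rest. Of 18 lists tested, 8 passed with the preset correlation, 0 with an estimated correlation (smallest adjusted p = 0.309) and 1 by fry.

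In cycling-like cells, Igfbp4 rose and the replication-dependent histone genes H3c7 and H2ac13 fell. Igfbp4 stood at 2.63 ± 2.05 CPM (SD, n = 2) in control and 39.3 ± 14.3 CPM (SD, n = 3) in mutant cultures (log2 fold change 3.81, SE 0.48, edgeR adjusted p = 0.0110), from 2 and 8 counts against 142, 56 and 35. H3c7 stood at 69.0 ± 6.99 CPM in control and 25.4 ± 1.45 CPM in mutant cultures (−1.47, SE 0.16, adjusted p = 0.00313), and H2ac13 at 123 ± 43.7 and 52.5 ± 5.23 CPM (−1.24, SE 0.19, adjusted p = 0.0473). Histone genes are near-identical copies, so counts split among them are uncertain. Igfbp4 lies at chromosome 11, positions 99041244 to 99054392 on the plus strand, and H2ac13 at chromosome 13, positions 21716422 to 21716814 (mm10). The edgeR test took 9021 genes, of which 427 reached an unadjusted p under 0.05 against 451 given by chance, and groups did not overlap in 1824 genes (20.2%; chance gives 20%). DESeq2 called 5 genes, 1 higher and 4 lower, the others being H1f5 and H3c3. Igfbp4 no longer passed without mutant culture 3 (3.78, adjusted p = 0.199), with MULTIseqDemux calls (2.90, adjusted p = 0.0974) or with hashtags scaled within each cell (2.50, adjusted p = 0.184). H3c7 no longer passed with MULTIseqDemux calls (−0.78, adjusted p = 0.977), with scaled hashtags (−1.11, adjusted p = 0.184) or with hormone genes left out of clustering (−1.11, adjusted p = 0.0570). H2ac13 no longer passed without control culture 2 (−0.82, adjusted p = 0.352), mutant culture 2 (−1.15, 0.144) or mutant culture 3 (−1.25, 0.488), nor under 7 other alternatives (adjusted p from 0.0756 to 1). Leaving out control culture 1 raised the count to 8 genes and mutant culture 1 to 12, and leaving out mutant culture 3 left H3c7 alone.

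In stem-like cells, Igfbp4 rose and was the sole gene called among 7645. It stood at 9.77 and 10.2 CPM in the control cultures and at 69.9 ± 35.2 CPM (SD, n = 3) in mutant cultures (log2 fold change 2.76, SE 0.37, edgeR adjusted p = 0.00565). DESeq2 also called 1 gene, and 448 genes reached an unadjusted p under 0.05 against 382 given by chance. Groups did not overlap in 1566 genes (20.5%; chance gives 20%). Igfbp4 no longer passed without control culture 1 (2.73, adjusted p = 0.0521) or control culture 2 (2.80, adjusted p = 0.0751), each of which left 1 control culture assumed to vary like the mutants, nor with MULTIseqDemux calls (2.49, adjusted p = 0.131) or hashtags scaled within each cell (1.51, adjusted p = 0.654). Without control culture 1 the genes passing were Col16a1 and Ly6e, without control culture 2 there were 0, and without mutant culture 3 they were Igfbp4 and Gm45713. Without mutant culture 1, 12 genes passed, among them the glycolytic enzymes Eno1, Tpi1, Gapdh, Ldha, Aldoa and Pgk1.

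In enterocyte-like cells no gene passed among 7228 in edgeR, with 185 at an unadjusted p under 0.05 against 361 given by chance and 0 by DESeq2. The smallest p values above zero were those of Ly6e (log2 fold change 1.37, SE 0.32), Fam214b (1.33, SE 0.34) and Rbp7 (1.54, SE 0.44), and those below zero of Ereg, the growth factor epiregulin (−2.60, SE 0.71), Sdcbp2 (−0.64, SE 0.18) and Gm11808 (−0.61, SE 0.17), all with adjusted p = 1. With hashtags scaled within each cell the value of Ly6e was −0.24, and 2 genes passed without control culture 1 and 3 without mutant culture 2. Etv1 had too few counts for the test in stem-like, cycling-like and enterocyte-like cells.

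The genotype effect differed between stem-like and cycling-like cells for Mki67 and H1f5, both among the fixed markers of cycling. Mki67, the proliferation marker Ki-67, stood at −0.23 in cycling-like and 1.5 in stem-like cells, a difference of 1.78 (SE 0.29, edgeR with culture as a block, adjusted p = 0.00337). In stem-like cells its level was 6.75 and 15.9 CPM in control and 38.4, 35.5 and 26.2 CPM in mutant cultures. H1f5, a linker histone, stood at −0.58 in cycling-like and 0.69 in stem-like cells, a difference of 1.30 (SE 0.25, adjusted p = 0.0216). The fit took 8976 genes with 3 residual degrees of freedom, and 468 genes reached an unadjusted p under 0.05. With 1 culture left out at a time, 7 and 5 genes passed without control cultures 1 and 2, and 6, 5 and 18 without mutant cultures 1, 2 and 3. Mki67 no longer passed without control culture 1 (1.32, adjusted p = 0.109). H1f5 no longer passed without control culture 2 (1.02, adjusted p = 0.550), mutant culture 1 (1.23, 0.0646) or mutant culture 2 (1.27, 0.0908). With finer clustering, at Leiden resolution 1.2, the difference was 1.56 for Mki67 (adjusted p = 0.0398) and 0.41 for H1f5 (adjusted p = 0.920). At the coarser resolution of 0.4 it was 1.48 for Mki67 (adjusted p = 0.0293) and 1.04 for H1f5, which no longer passed (adjusted p = 0.129). Cells had been sorted into these classes partly by the same genes.

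Cell type shares did not differ past the test. Enteroendocrine-like cells made up 4.48% ± 0.666 of control (SD, n = 2) and 3.25% ± 0.790 of mutant cultures (SD, n = 3; log2 ratio −0.49, edgeR adjusted p = 0.422). Cycling-like cells made up 17.1% ± 1.80 and 21.2% ± 7.58 (log2 ratio 0.33) and enterocyte-like cells 14.2% ± 3.51 and 18.3% ± 4.35 (0.38). Goblet/Paneth-like cells made up 8.11% ± 2.71 and 7.16% ± 3.51 (−0.24) and stem-like cells 21.7% ± 1.76 and 17.1% ± 4.47 (−0.36). Cluster 2 cells made up 13.9% ± 0.548 and 13.2% ± 5.78 and cluster 6 cells 17.5% ± 2.01 and 12.3% ± 2.85 (−0.49). Cluster 9, the cells of lowest depth, was nearest to the threshold at 3.11% ± 0.461 of control and 7.55% ± 1.70 of mutant cultures (1.29, adjusted p = 0.0626), and it passed without mutant culture 3 (1.44, adjusted p = 0.00809), as did cycling-like cells (0.57, adjusted p = 0.048). The goblet/Paneth-like ratio was 0.16 without control culture 2. In edgeR 0 of 8 classes and 0 of 10 clusters passed, with 1 of each at an unadjusted p under 0.05, and the exact permutation test, whose smallest p here is 0.1, called 0. The sort gate and the cell filter can set these shares.

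**Figure D3:**
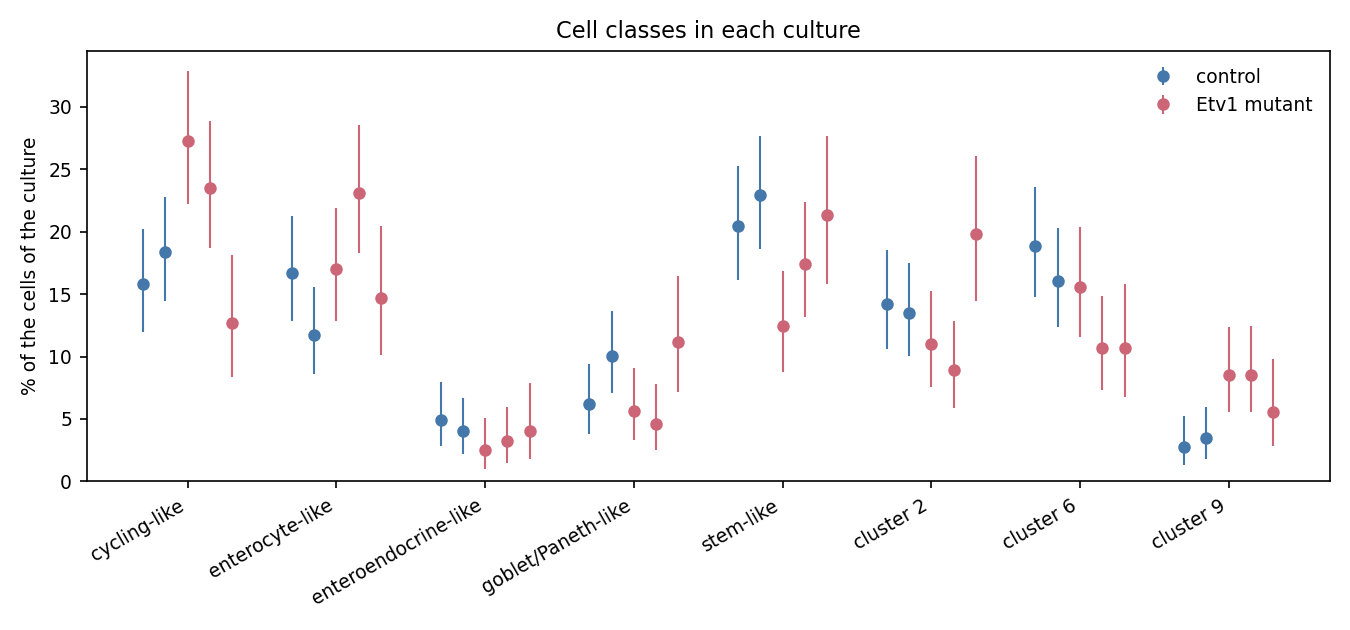
Percent of cells in each named class and unnamed cluster per culture, with exact 95% binomial intervals that cover counting error only; points are the 2 control and 3 mutant cultures. Cluster 9 averages 3.11% in control and 7.55% in mutant cultures.

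Cells with a hormone transcript were counted after thinning each enteroendocrine-like cell to 5289 UMIs, which left out 1 and 2 control and 1, 1 and 1 mutant cells. Pyy was found in 3 of 15 and 3 of 12 control cells and in 0 of 6, 0 of 8 and 0 of 7 mutant cells, 22.5% ± 3.54 (SD, n = 2) against 0% (exact two-sided permutation test, p = 0.1, the smallest possible with 2 and 3 cultures). At this depth, counts of 0 allowed shares of cells with a Pyy UMI of up to 50%, 37.5% and 42.9% in the 3 mutant cultures. Without thinning, Pyy was found in 3 of 16 and 4 of 14 control and 0 of 7, 2 of 9 and 1 of 8 mutant cells. Enterocyte-like cells, which should lack Pyy, gave a background of 3 of 212 cells (1.42%; median 27038 UMIs against 9694 in enteroendocrine-like cells). Sct was found in 67.5% ± 10.6 of control and 47.6% ± 4.12 of mutant cells (exact p = 0.1; background 4.72%) and Tph1 in 21.7% ± 7.07 and 4.76% ± 8.25 (exact p = 0.2). Gcg (15.8% and 8.93%, exact p = 0.6), Cck (22.5% and 18.7%, 0.5), Nts (3.33% and 4.17%, 1), Ghrl (11.7% and 4.76%, 0.5) and Tac1 (13.3% and 10.3%, 1) differed by less, and Gip and Sst were found in 0 of these cells. Culture shares did not overlap between the genotypes for 3 of the 10 hormone genes. Chance gives 20% only for values without ties. Since Gip and Sst were 0 in every culture and other genes tied at 0, that level does not apply here. Among all cells thinned to 3800 UMIs, Sct was found in 8.86% ± 0.361 of control and 5.98% ± 1.43 of mutant cells (exact p = 0.2), and Pyy in 1.59% and 1.19% (exact p = 0.7), close to its background of 1.35%.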

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

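Of the tests in this part, those of class makeup for Pyy and Igfbp4, of chance and of the chromosome 11 region for Pyy, and of the class border for H1f5 were chosen only after the results were seen.

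Pyy was lower in the mutant cultures over all cells and within enteroendocrine-like cells. For the fall over all cells, a smaller share of enteroendocrine-like cells was not tested separately. The log2 fold change of −8.37 within them is itself a flagged call and rests on 1 cell per control culture. The class share had a log2 ratio of −0.49 (edgeR adjusted p = 0.422), a much smaller fall than that of Pyy. With so few Pyy-rich cells, that does not exclude it. A change of the surrounding chromosome 11 region is not settled. Over all cells, 2 of 187 genes (1.07%) within 5 Mb of Pyy or Igfbp4 had a low unadjusted p, against 3.05% of 10872 genes elsewhere. In stem-like cells the share was 6.92% against 5.83% elsewhere. So few genes cannot decide it. Too few Pyy-rich cells captured by chance stays open: all 4 fell among the 30 control cells, with a chance of 0.0867, and no outcome with 4 such cells could have come below the bound of 0.00714. The value within the class also cannot show whether the makeup of the class itself differed. Progenitor markers stood above zero there in 4 of 4, without passing at an estimated correlation. Cells of the class with Neurog3 but no Chga or Chgb UMI occurred in every mutant culture and in control culture 2, but not in control culture 1. They were a larger part of the class in each mutant culture than in either control culture, which was not tested. Lower Pyy in Etv1 mutant cells, fewer cells of the class, a different makeup within it and uneven capture of Pyy-rich cells stay open. They cannot be told apart with these cells.

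Igfbp4 was higher in stem-like and cycling-like cells of the mutant cultures, and in clusters 2 and 6. The log2 fold changes of at least 2.76 within both classes are the flagged calls themselves, so they give no separate test of culture makeup. A few Igfbp4-rich cells as the source are argued against by thinned shares of at least 27.8% of stem-like cells in each mutant culture. The shares in control were 9.84% and 8.57%. A change of the chromosome 11 region cannot be told apart from a change of Igfbp4 itself. In stem-like cells 6.92% of 130 genes near Igfbp4 or Pyy had a low unadjusted p against 5.83% elsewhere (exact hypergeometric test, p = 0.350). The call in stem-like cells (2.76, SE 0.37) ended with MULTIseqDemux calls (adjusted p = 0.131) at 2.49 (SE 0.44), a fold within its spread of the first, and with scaled hashtags (0.654) at a smaller 1.51 (SE 0.31). Whether hashtag assignment bears on it was not tested further.

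The mutant effect differed between stem-like and cycling-like cells, in a test of the difference itself, for Mki67 (1.78) and H1f5 (1.30). For Mki67 the difference stayed at 1.48 or more at both other clustering resolutions. These regroup the same cells by the same genes, so they cannot exclude a border between the classes that shifts with genotype. Hmgb2, Cenpf and Cenpa, among the next smallest p values, also stood lower in cycling-like and higher in stem-like cells, without passing. Doublets are argued against by a ratio of 1.12 between the median UMIs of mutant stem-like cells with and without Mki67. The ratio was 1.29 in mutant culture 3 and 0.970 and 1.07 in mutant cultures 1 and 2. For H1f5 the difference came down to 0.41 at the finer resolution, so the class border may account for it. More Mki67 in mutant stem-like cells may be biological and is only a hypothesis, since the call was lost without control culture 1 (1.32, adjusted p = 0.109). The share of stem-like cells with an Mki67 UMI was 10.6% and 21.2% in control and 48.6%, 30.6% and 31.0% in mutant cultures.

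Hormone transcripts also lay in the 1054 filtered barcodes with no HTODemux call, which entered no comparison made with those calls. They held 1849 UMIs of Gcg, 698 of Pyy, 357 of Cck and 810 of Nts. For Sct, Ghrl, Tac1 and Tph1 the numbers were 1533, 525, 28 and 25. Barcodes with at least 3 UMIs numbered 2 for Gcg, 3 for Pyy, 6 for Cck, 1 for Nts, 15 for Sct and 3 each for Ghrl, Tac1 and Tph1. HTODemux gave them no genotype. Before the cell filter, MULTIseqDemux placed 106 barcodes without an HTODemux call in control culture 1 and 0 in control culture 2. It placed 29, 135 and 85 in mutant cultures 1, 2 and 3. Which of these held the hormone UMIs was not examined.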

How the results depend on the processing

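Scaling hashtags within each cell, leaving out the cell richest in Pyy, leaving hormone genes out of clustering in gene tests and testing the remaining clusters were chosen after seeing the data. Of all recomputed values 1513 kept direction and side of the threshold or, for counts or shares, stayed near the main value. These include values that passed in neither fit. Of the rest, 80 no longer passed, 29 newly passed, 36 reversed and 83 moved. Except where named, the cause was not tested.

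Over all cells the 1 gene called became 9 with DESeq2, 2 with no count filter, 0 with the 70% rule, 2 with MULTIseqDemux, 2 with scaled hashtags and 0 without the Pyy-rich cells. With equal cells the count stayed at 1, but the gene was Defa32, and Pyy no longer passed (adjusted p = 1). In enteroendocrine-like cells 1 became 2 with DESeq2, 35 with no count filter, 2 with MULTIseqDemux, 3 with equal cells, 2 with scaled hashtags and 0 without the Pyy-rich cells. The 1 hormone gene passing over its list became 7 with no count filter, 2 with MULTIseqDemux, 2 with equal cells, 4 with scaled hashtags and 0 without the Pyy-rich cells. In cycling-like cells 3 became 5 with DESeq2, 39 with no count filter, 0 with MULTIseqDemux, 7 with no cell filter, 6 with the stricter filter, 6 with equal cells, 1 with scaled hashtags and 1 with hormone genes out of clustering. In stem-like cells 1 became 20 with no count filter, 0 with MULTIseqDemux, 2 without Scrublet doublets and 0 with scaled hashtags, and in enterocyte-like cells 0 became 49 with no count filter. The 2 genes of the class term became 25 with no count filter and 7 at Leiden resolution 1.2. Lists passing fell from 13 to 0 with an estimated correlation and 1 by fry over all cells, and from 8 to 0 and 1 in enteroendocrine-like cells. Clusters passing in share went from 0 to 1 with TMM. Hormone genes whose shares of all cells did not overlap went from 2 to 1 with no thinning, 4 at a threshold of 3 UMIs, 0 with the 70% rule and 4 with scaled hashtags.

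Reversed over all cells were Rps27l (−0.08) and Fos (−0.21) with the 70% rule, Cck (0.97), Adm (−0.09) and Spink4 (0.03) with MULTIseqDemux, Amn (−0.02) with scaled hashtags, and Gcg (0.89) and Nts (1.72) without the Pyy-rich cells. Reversed in enteroendocrine-like cells were Gcg without the 20 most abundant genes (0.03), with the stricter filter (0.01) and without the Pyy-rich cells (1.09), Cck (1.48), Tac1 (0.20) and Defa24 (−0.99) with MULTIseqDemux, and Tac1 (0.53) and Defa24 (−0.26) with scaled hashtags. Ly6e in enterocyte-like cells was −0.24 with scaled hashtags, and the cycling-like share −0.23 with the 70% rule and −0.20 with MULTIseqDemux. Newly passing hormone genes were Sct with MULTIseqDemux (−2.43, adjusted p = 0.0216) and Cck with scaled hashtags (−6.65, 0.0142) over all cells. In enteroendocrine-like cells they were Cck with equal cells (−10.55, 0.00152) and scaled hashtags (−9.30, 0.00194), and Sct (−2.37), Ghrl (−3.60) and Tph1 (−2.36) with no count filter.

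With each culture left out in turn, genes called ranged from 1 to 6 over all cells, 1 to 9 in enteroendocrine-like, 1 to 12 in cycling-like, 0 to 12 in stem-like and 0 to 3 in enterocyte-like cells, hormone genes from 1 to 4, the class term from 5 to 18, classes in share from 0 to 2 and clusters from 0 to 1, and non-overlapping hormone shares from 3 to 5 in enteroendocrine-like and 2 to 6 in all cells. Over all cells Gcg ranged from −1.68 to 0.42, Cck from −2.11 to 0.72, Nts from −7.68 to 5.89, Ghrl from −4.61 to 3.98, Tac1 from −2.09 to 4.08, Tph1 from −3.07 to 0.21 and H1f5 from −0.58 to 0.01. In enteroendocrine-like cells Gcg ranged from −1.51 to 1.38, Cck from −1.54 to 1.78, Ghrl from −4.45 to 6.0 and Tac1 from −1.40 to 7.10. The goblet/Paneth-like share ranged from −0.66 to 0.16. The 70% rule left 0 cells of the enteroendocrine-like, cycling-like, stem-like and enterocyte-like classes in some culture and gave no value there. No paired analysis was possible because the control and mutant cultures carry different hashtags and no shared replicate numbers.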

Other observations

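Tests of the clusters outside the fixed classes, and every gene group named in this part, were chosen after the results were seen. Ly6e, a surface protein, was higher in mutant cultures in all 4 remaining clusters. It passed in cluster 6, which had mitochondrially encoded genes among its top 10 (log2 fold change 1.65, edgeR adjusted p = 0.0434). Its other values were 1.35 in cluster 2, 1.85 in goblet/Paneth-like cells and 1.45 in cluster 9, none of which passed. Control culture 1 stood above control culture 2 each time, for example 79.9 against 23.2 CPM in cluster 6, where mutant cultures held 180.3, 170.6 and 116.5 CPM. Igfbp4 passed in cluster 2 (2.99, adjusted p = 0.00347) and in cluster 6 (2.64, adjusted p = 0.0407). Cluster 6 also had more Nfkbia, the inhibitor that NF-kB induces (1.64, adjusted p = 0.00845), and less Gm11808 (−0.83, adjusted p = 0.0434), whereas DESeq2 called 0 genes there and 283 reached an unadjusted p under 0.05 in edgeR.

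Cluster 9, the cells with few UMIs, had more Fos, an immediate early transcription factor (3.83, adjusted p = 0.00316), Fads2, a fatty acid desaturase (3.15, adjusted p = 0.0235), and Gm45713 (2.16, adjusted p = 0.0235) in the mutant cultures. Jun, the partner of Fos, did not pass (2.65, adjusted p = 0.0522). The cluster held 78361 and 79255 UMIs in 9 and 12 control cells, against 42079, 97381 and 29590 UMIs in 24, 24 and 11 mutant cells. Its cells were thus shallower in the mutant cultures, and these changes were not separated from that difference. In this cluster DESeq2 called 6 genes, 5 higher and 1 lower. In goblet/Paneth-like cells no gene passed in edgeR, with 203 at an unadjusted p under 0.05 and 1 called by DESeq2. The lowest p values there included those of Muc2 (−2.19) and Areg, an epidermal growth factor receptor ligand (−2.31), both with an adjusted p of 0.700.

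Pyy in cells rich in Gcg was not tested between the genotypes, since there were too few such cells. The Gcg-rich cell of control culture 1 held 927 Pyy UMIs. Of the 2 in control culture 2, 1 held 895 Pyy UMIs and the other, with 943 Gcg UMIs, held 0. The 1 each of mutant cultures 2 and 3 held 1 Pyy UMI beside 1655 and 519 Gcg UMIs.

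Kdm5d, a gene of the Y chromosome, was found in 14.6% of cells of control culture 1, 1.72% of control culture 2, and 13.8%, 17.8% and 6.60% of mutant cultures 1, 2 and 3. With hashtags scaled within each cell, 42 of the 515 cells placed in control culture 2 (8.16%) held a Kdm5d UMI, against 6 of 349 with the calls used throughout. The cells that scaling added there thus held Kdm5d more often, and whether they belong to other cultures was not tested. With MULTIseqDemux calls it was 5 of 215 (2.33%). This doubt bears on every value given with scaled hashtags, whether a call ended, was gained or reversed there. It does not show that the calls used throughout are free of misplaced cells. The labels do not give the sex of the mice, so a difference in sex between the cultures stays open.

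In the 12 glycolysis genes the median level as a percent of the control mean was 105% and 95.1% in the control cultures and 124%, 65.3% and 88.7% in mutant cultures 1, 2 and 3. In 9 other hypoxia targets it was 109% and 90.6%, against 140.1%, 57.5% and 93.8%. Replicates thus differed more within the mutant group than between the genotypes.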
